A study of Homo sapiens with 10 samples.

How the data were processed

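Gene expression was measured by RNA-seq in 10 libraries of C42b cells, a human prostate cancer line, after 72 h with nanoparticles. Per the labels, 5 libraries came from cells given empty nanoparticles and 5 from cells given nanoparticles loaded with NT-PGC1a mRNA, and all carry the same batch label. The series' design text names the line C42, while the labels of the 10 samples give C42b. Which of these is right was not tested, and the name in the labels is used here. Total RNA was extracted with a column kit and cleaned on a second column, per the labels' protocols. The same protocols name both an mRNA and an RNA library preparation kit of one maker without saying which was used, so whether libraries were selected for poly(A) RNA is not given in the sources used here. The authors used cutadapt 4.1, Salmon 1.10.2 and DESeq2 with the genome build GRCh38, per the submitters' processing notes. The version of the authors' DESeq2, the role and order of the tools, the annotation release and the strand setting are not given in the sources used here.

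The authors deposited a table of log2 values that the labels call rlog, the regularized log2 transform of DESeq2, for 35936 genes in each of the 10 libraries. In that transform the authors' counts are divided by size factors and the differences of weakly expressed genes are shrunk towards the gene's mean, so a fold change of such a gene is understated here. Values ran from -2.16 to 19.3. The table's further pair of columns equalled the median of each group's 5 values exactly and was not used in any test. No counts were among the values analysed, so the depth of each library is unknown, and no counting interval or detection floor is given. Precision was therefore judged from the spread between libraries. The standard error of the log2 difference had a median of 0.10 over the tested genes, and 0.034 at the lowest. Of the gene identifiers, 24097 carried a symbol in the table and 28044 had one after matching to a reference list of gene names. Coordinates are those of GENCODE 29 on GRCh38, which may not be the annotation behind the deposited values.

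Differences are NT-PGC1a minus empty throughout. Genes with a mean rlog of at least 4 over the 10 libraries were kept, which left 15629. They were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a mean-variance trend, no covariate, and Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05. Adjusted p-values of genes are from that fit unless another test is named. Confidence intervals of single genes are at 95 percent. An exact two-sided permutation test over the 252 relabellings of the 10 values was run beside it, and the smallest p it can give is 0.00794. 36 gene lists and 6 lists of markers of other cell types were fixed before the data were examined. The 35 lists with at least 5 measured members were tested with limma's camera against all other tested genes, with its preset correlation of 0.01 between genes, two-sided and adjusted over the 35 lists. Camera was repeated with the correlation estimated from the data, and fry was run as a test within each list. Counts of members that rose or fell use the adjustment over all tested genes, and counts adjusted over the list alone are given beside them. 25 genes belong to more than 1 list.

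The genes named were chosen by a rule fixed before the data were examined. It takes PPARGC1A, the 8 genes with the highest and the 8 with the lowest log2 difference among called genes whose groups do not overlap, the 3 members with the smallest p of each list past the threshold, up to 2 such members of other lists, and a fixed set of 16 genes tied to PGC-1α, androgen response, MYC, interferon and stress. Unnamed identifiers, clone-style symbols and pseudogenes were left out of the part on size. Some lists that did not pass are given as counts only. Genes named outside the rule are said to have been chosen after their values were seen. A few genes that the rule or a count would name are not reported here.

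The fit was tested on simulated data for the comparison of NT-PGC1a with empty over 15629 genes. It recovered 27 of 50 genes changed by 0.5 on the log2 scale, 46 of 50 changed by 1, and all 50 at each of 2 and 4. It made 12 false calls among 15429 unchanged genes, and 0 calls in a simulation with no change. Camera called 2 lists when the p53 targets alone had been shifted. In all of these simulations the noise was independent between genes and between libraries, and no library was displaced. They therefore do not show the error rates for real libraries with correlated genes. The alternatives were other filters on low values, median centring, quantile normalization, other variance models, library weights, a floor on low values, a required effect size, the exact permutation test, the replicate number as a block, and leaving out each library in turn. After the data had been seen, further alternatives were added. They are the removal of a trend with GC content and transcript length in each library, camera with an estimated correlation without 1 library, the list of mitochondrial biogenesis without PPARGC1A, and the alternatives for the 2-fold counts and for the direction of each list. GC content and length were found for 96.2% of the tested genes. No sample was left out of the main comparison.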

Results

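The transcriptomes of 10 libraries of cells labelled C42b, a derivative of the LNCaP prostate cancer line, were compared after 72 h with nanoparticles. 5 libraries came from cells given empty nanoparticles. The other 5 came from cells given nanoparticles loaded with mRNA for NT-PGC1a, the short N-terminal form of PGC-1α, a transcriptional coactivator that drives genes of mitochondrial metabolism. The comparison addresses how gene expression differs when the carrier brings that message. The labels give the replicates numbers and 1 batch but do not say that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Expression was available as regularized log2 (rlog) values without counts, so the depth of each library is unknown. No pair of libraries was identical, and the smallest SD of the differences between any 2 of them was 0.15 on the log2 scale over the 15629 genes tested.

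PPARGC1A, the gene that encodes PGC-1α, was higher in all 5 NT-PGC1a libraries. Its rlog value was 9.24 ± 0.11 (SD, n = 5) with empty nanoparticles and 13.53 ± 0.43 (SD, n = 5) with NT-PGC1a, a log2 difference of 4.29 ± 0.17 (SE) or 19.6-fold (95% interval 3.92 to 4.67 on the log2 scale, limma adjusted p = 5.77e-07, exact permutation p = 0.00794). The empty libraries ran from 9.09 to 9.40 and the NT-PGC1a libraries from 12.80 to 13.94. The gene (ENSG00000109819) lies on chromosome 4 from 23755041 to 23904089, on the minus strand. The deposited values are per gene, so delivered message and the cells' own transcripts were not separated.

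With PPARGC1A included, 6969 of 15629 genes changed (44.6%), of which 3534 were higher and 3435 lower with NT-PGC1a. At least 2-fold differences were seen for 271 higher and 123 lower genes. These counts were 478 and 347 without empty replicate 3, and 229 and 81 without empty replicate 1. The groups did not overlap at all for 2345 genes, where chance gives 124 (0.794%). The library labelled empty replicate 3 stood apart from its group. On the first principal component, which held 76.4% of the variance, the other 4 empty libraries lay between -38.3 and -36.9, the NT-PGC1a libraries between 18.6 and 27.8, and empty replicate 3 at 26.0. Across genes its correlation was 0.992 to 0.997 with the NT-PGC1a libraries and 0.980 to 0.981 with the other empty libraries. Its PPARGC1A value, 9.40, was the highest of the empty group, 0.21 above the mean of the other 4. That is 4.86% of the way to the NT-PGC1a mean. Without that library 10662 genes changed, 5499 higher and 5163 lower, and 6967 of the 6969 calls were shared in the same direction. Leaving out another empty library instead moved the count to 4564 (replicate 1), 4521 (replicate 2), 4300 (replicate 4) or 4406 (replicate 5).

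**Figure D1:**
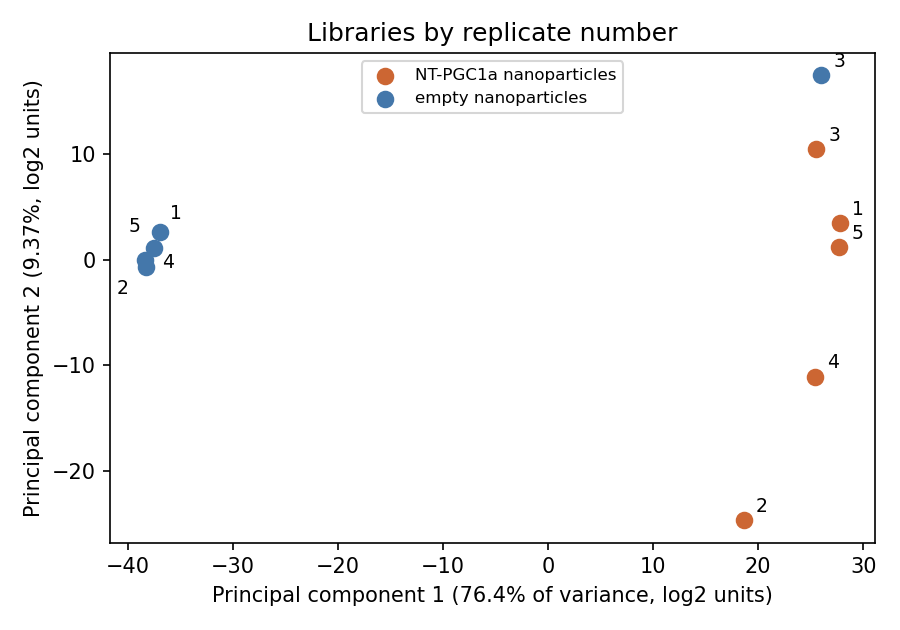
Position of the 10 libraries on the first 2 principal components of the tested genes (log2 units, with the share of variance on each axis). Points are libraries numbered by replicate, blue for empty and orange for NT-PGC1a nanoparticles. 4 empty libraries lie at -38.3 to -36.9 on the first component, and empty replicate 3 lies at 26.0 among the NT-PGC1a libraries.

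Among genes whose groups did not overlap, the highest rises after PPARGC1A were those of 2 interferon-stimulated genes and 5 others. ANGPT2, a secreted ligand of the endothelial receptor TIE2 (chromosome 8, 6499651 to 6563409), rose by 2.84 ± 0.49 (log2, SE), or 7.14-fold, with an adjusted p of 0.00361. FOS, a subunit of the AP-1 transcription factor (chromosome 14, 75278774 to 75282230), rose 6.14-fold. TCIM rose by 2.53 ± 0.41, MRGPRE, an orphan receptor gene, by 2.53 ± 0.46, and ENC1, which encodes an actin-binding protein, by 2.47 ± 0.35. In empty replicate 3 these 5 genes had already moved between 63.1% (FOS) and 86.5% (MRGPRE) of the way from the other empty libraries to the NT-PGC1a mean. The deepest falls were smaller. FAM229A (chromosome 1, 32361270 to 32364278) fell by 1.58 (log2) and CCDC146 (chromosome 7, 77122434 to 77329533) by 1.40. LBR, the lamin B receptor of the inner nuclear membrane (chromosome 1, 225401502 to 225428925), differed by -1.19 ± 0.20 (adjusted p = 0.00369). PDE3B, a cyclic nucleotide phosphodiesterase gene, differed by -1.16 ± 0.19. RFXAP, which encodes a regulator of MHC class II genes, and GYG2, a glycogenin gene, each differed by -1.15. PDK3, a pyruvate dehydrogenase kinase gene, differed by -1.15 ± 0.23. SH3BP5-AS1 differed by -1.16 ± 0.23, but it is antisense to another gene and the strand setting of the counting is not given, so reads of the pair could not be told apart. For the genes that fell, empty replicate 3 lay 34.6% (CCDC146) to 87.1% (PDK3) of the way. Rises and falls alike were taken only from genes whose groups did not overlap. Empty replicate 3 therefore could not reach or pass the NT-PGC1a mean in them.

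Interferon-stimulated genes, which cells switch on when they sense foreign RNA or interferon, rose. Of 34 measured members 15 rose and 3 fell (15 and 4 adjusted over the list alone), with a median log2 difference of 0.25 (camera adjusted p = 0.00349). With an estimated correlation the list's adjusted p = 0.614. IFIT2, IFIT3 and IFIT1, which encode proteins that bind viral RNA, rose most within the list. IFIT2 went from 6.71 ± 0.19 to 9.80 ± 0.28 (SD, n = 5 each), a rise of 8.55-fold (limma adjusted p = 1.08e-06), IFIT3 rose by 2.59 ± 0.13 and IFIT1 by 2.41 ± 0.15 (log2, SE). The 3 genes are neighbours on chromosome 10, where IFIT2 starts at 89283694 and IFIT1 ends at 89406486. OASL rose by 2.16 ± 0.10 and ISG15, a ubiquitin-like modifier, by 0.85 ± 0.09. In empty replicate 3 these genes lay between -21.4% (IFIT1) and 31.6% (ISG15) of the way to the NT-PGC1a mean. Of the 19 members that rose without that library, 12 lay over 50% of the way in it and 6 under 25%, and the median over the 19 was 80.0%. The members averaged 0.14 above the other empty libraries in empty replicate 3, against 0.53 in the NT-PGC1a group. STAT2, PARP14 and BST2 were the 3 that fell, and are named after their values were seen, and 6 fell without empty replicate 3. The preset camera call was lost with library weights (adjusted p = 0.0728). In the list of type I and III interferons and RNA sensors, 3 of 8 measured members rose and 3 fell (3 and 3 adjusted over the list alone), and it did not pass (camera adjusted p = 0.940).

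**Figure D2:**
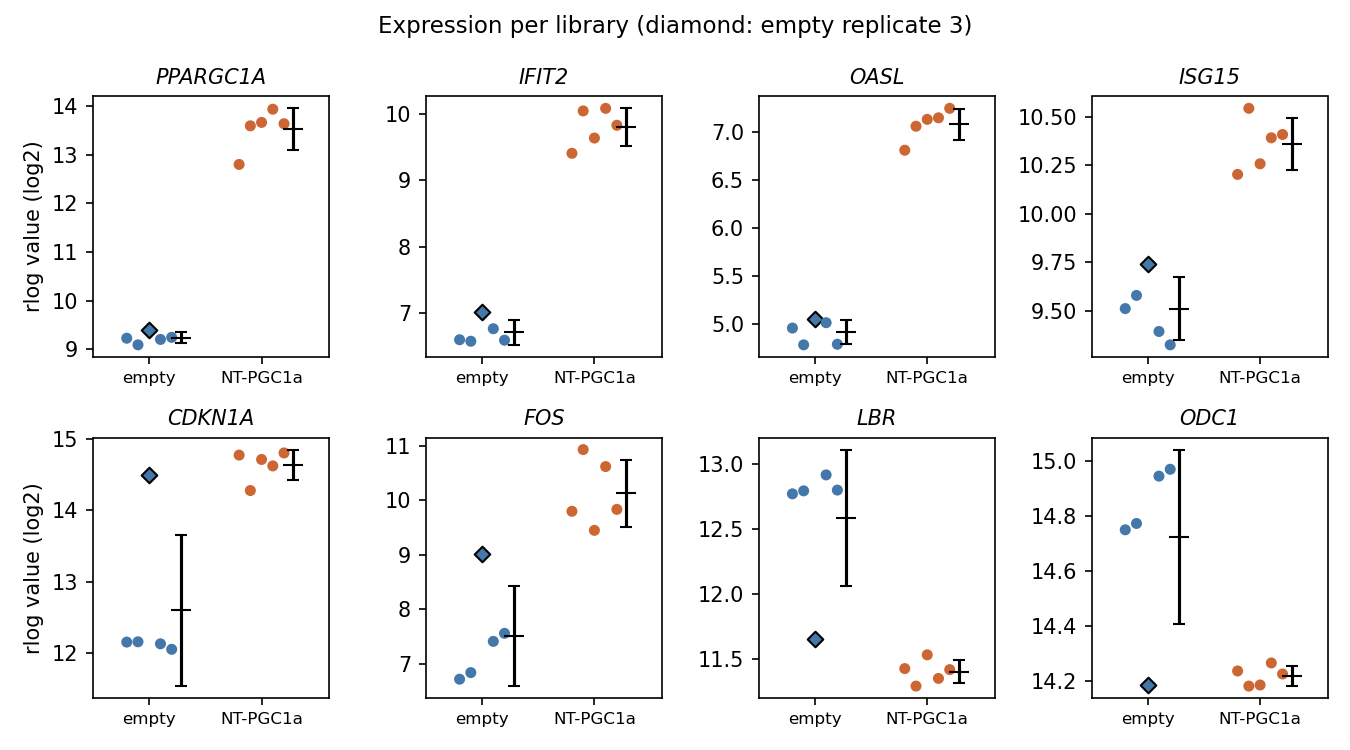
Expression of 8 genes in each library on the rlog (log2) scale, blue for empty and orange for NT-PGC1a nanoparticles, with the mean and SD of each group of 5 beside the points and empty replicate 3 drawn as a diamond. For PPARGC1A, IFIT2, OASL and ISG15 empty replicate 3 is the highest empty library but lies below every NT-PGC1a library. Its CDKN1A (14.49) and ODC1 (14.19) values lie away from the other empty libraries.

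Targets of the tumour suppressor p53 rose as a group. 24 of 27 members rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 7.19e-09). The adjusted p = 0.614 with an estimated correlation. The CDK inhibitor gene CDKN1A rose by 2.04 ± 0.41 (log2, SE, adjusted p = 0.00577). FAS, a death receptor gene, rose by 1.19 ± 0.18, the phosphatase gene PPM1D by 0.66 ± 0.11, and BTG2 by 0.67 ± 0.10. The members averaged 0.86 above the other empty libraries in empty replicate 3 and 0.98 in the NT-PGC1a group. Among apoptosis regulators 13 of 23 rose and 1 fell (13 and 1 adjusted over the list alone), with a camera adjusted p of 0.0321 and an adjusted p of 0.614 with an estimated correlation. BBC3, which encodes the pro-apoptotic protein PUMA, rose by 1.53 ± 0.30 and BAK1, a pore-forming effector, by 0.66 ± 0.11. BCL2L1, which encodes the anti-apoptotic protein BCL-XL, also rose, by 0.36 ± 0.07. Without empty replicate 3, 4 fell. The list's mean in empty replicate 3 was 0.33 above the other empty libraries, against 0.35 with NT-PGC1a.

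Immediate early genes, which are transcribed within minutes of a stimulus, rose in 18 of 19 measured members with 0 falls (18 and 0 adjusted over the list alone, median 0.90, camera adjusted p = 8.48e-08). The adjusted p = 0.614 with an estimated correlation. Besides FOS and BTG2, EGR1 rose by 1.65 ± 0.19 (log2, SE) and ATF3, a stress-induced transcription factor gene, by 2.37 ± 0.53. Empty replicate 3 was 0.90 above the other empty libraries over these genes, against 1.20 in the NT-PGC1a group. Its ATF3 value lay 103.6% of the way to the NT-PGC1a mean, but its EGR1 value was 0.35 below the other empty libraries. Of the NF-kB and inflammatory genes 10 of 14 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.00267), with an adjusted p of 0.614 with an estimated correlation. The chemokine gene CCL2 rose by 1.89 ± 0.33, NFKBIA, which encodes the inhibitor of NF-kB, by 0.82 ± 0.14, and BCL3 by 0.58 ± 0.12. For this list empty replicate 3 stood 0.73 above the other empty libraries, against 0.78 with NT-PGC1a, and 12 members rose and 2 fell without that library.

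Genes of the cell cycle fell. In the G1/S and DNA replication list 19 of 38 members fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.000154). The adjusted p = 0.650 with an estimated correlation. The clamp loader genes RFC4 and RFC3 differed by -0.57 ± 0.10 and -0.34 ± 0.06, and the exonuclease gene EXO1 by -0.59 ± 0.11 (log2, SE). In the G2/M and mitosis list 25 of 36 fell and 1 rose, CDC25B, named after its value was seen (30 and 1 adjusted over the list alone). The median was -0.45 (camera adjusted p = 1.67e-08, and adjusted p = 0.633 with an estimated correlation). The mitotic kinesin genes KIF11 and KIF2C differed by -0.79 ± 0.12 and -0.44 ± 0.06, and the kinetochore gene NUF2 by -0.47 ± 0.06. The proliferation marker MKI67 had a log2 difference of -0.69 ± 0.28 and did not pass (adjusted p = 0.0658). It passed without empty replicate 3 (-0.96, adjusted p = 0.000389), without NT-PGC1a replicate 2 (-0.86, adjusted p = 0.0316) and with library weights (-1.14, adjusted p = 7.63e-08). Empty replicate 3 stood at -0.49 and -0.51 relative to the other empty libraries for the 2 lists, against -0.49 and -0.59 in the NT-PGC1a group.

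Replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail and accumulate in S phase, rose while the replication genes fell. 20 of 22 measured members rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 5.62e-10, and adjusted p = 0.614 with an estimated correlation). H1-2, a linker histone gene (chromosome 6, 26055787 to 26056428), rose by 1.86 ± 0.27, and H3C4 by 1.68 ± 0.23 (log2, SE), and H4C14 rose 2.14-fold. H3C4 was weakly expressed, with a mean rlog of 3.94 in the empty group, under the filter value of 4, and 5.62 with NT-PGC1a. Copies of these genes are nearly identical, so the value of a single copy is uncertain. Empty replicate 3 was 0.49 above the other empty libraries over the list, against 1.01 with NT-PGC1a. Among nuclear-retained and small noncoding RNAs, fixed as a sign of RNA quality, 7 of 11 measured rose and 0 fell (8 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 0.0321). The adjusted p = 0.614 with an estimated correlation, and the preset camera call also ended after removal of a GC and length trend (adjusted p = 0.0824). SNORD3A, the U3 small nucleolar RNA, rose by 1.28 ± 0.12, and the snoRNA host genes SNHG12 and GAS5 by 1.05 ± 0.26 and 0.58 ± 0.15. SNHG12 is annotated as antisense, and with the strand setting not given, reads of the opposite strand could not be set apart. MALAT1, a nuclear-retained RNA named after its value was seen, differed by -0.14 ± 0.08 and did not pass. Empty replicate 3 was 0.55 above the other empty libraries over this list, against 0.58 with NT-PGC1a.

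**Figure D3:**
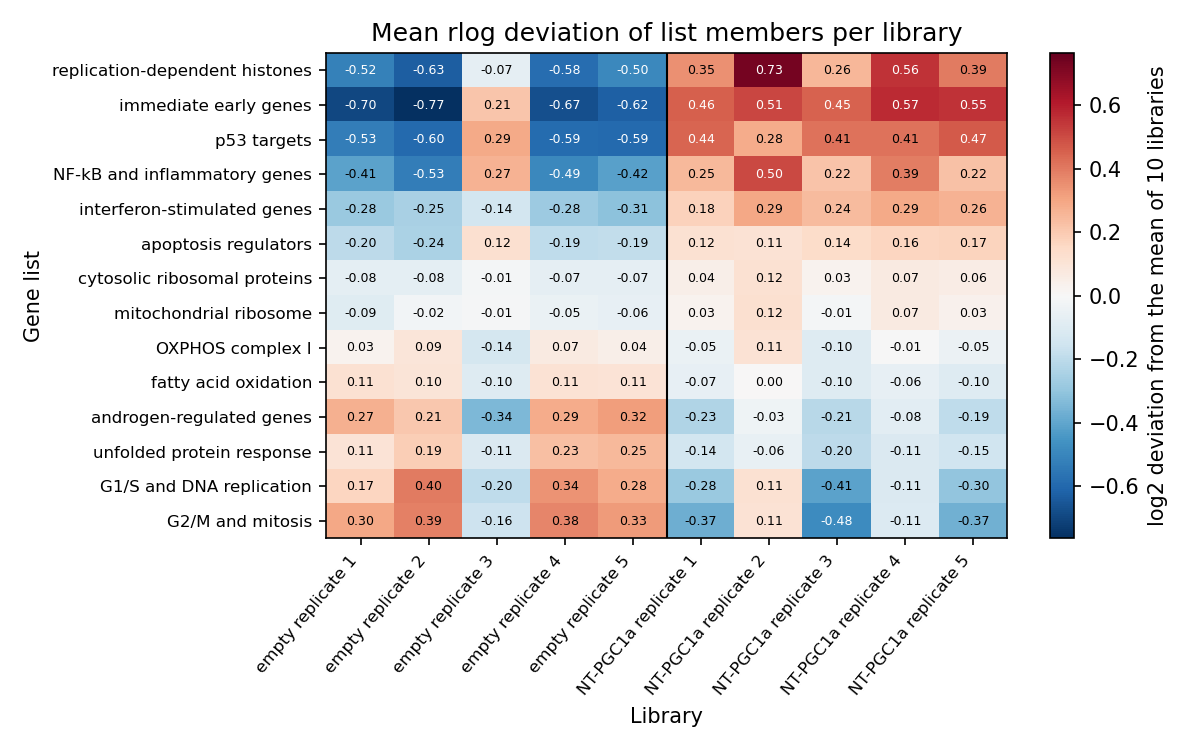
Mean deviation of the measured members of 14 gene lists from each gene's mean over the 10 libraries, in log2 units, 1 column per library and 1 row per list, red above and blue below. The vertical line separates the 5 empty from the 5 NT-PGC1a libraries. Empty replicate 3 has the sign of the NT-PGC1a group for the p53 targets (0.29) and that of the empty group for the interferon-stimulated genes (-0.14).

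Genes of the unfolded protein response, which encode chaperones and folding enzymes of the endoplasmic reticulum, fell in 14 of 24 members with 1 rise, DNAJB9, named after its value was seen (16 and 5 adjusted over the list alone, 17 and 5 without empty replicate 3). The median was -0.40 (camera adjusted p = 0.00404, and adjusted p = 0.614 with an estimated correlation). HSPA5, which encodes the chaperone BiP, differed by -0.52 ± 0.10, HYOU1 by -0.43 ± 0.06 and the ubiquitin ligase gene SYVN1 by -0.57 ± 0.09 (log2, SE). The list stood at -0.30 in empty replicate 3 and -0.33 in the NT-PGC1a group, relative to the other empty libraries. In the integrated stress response list 11 of 32 rose and 7 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.680). In the heat shock list 4 of 16 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.479), and without empty replicate 3 6 rose and 3 fell.

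Among androgen-regulated genes 9 of 28 measured members fell and 3 rose (9 and 3 adjusted over the list alone), with a median of -0.23, and the list did not pass (camera adjusted p = 0.118). Without empty replicate 3 17 fell and 4 rose, with a median of -0.34, a camera adjusted p of 0.00587 and an adjusted p of 0.494 with an estimated correlation. ZBTB10 and CENPN rose, by 0.71 ± 0.16 and 0.31 ± 0.06, and FKBP5 (-0.68), named after its value was seen, was among those that fell. KLK3, which encodes prostate-specific antigen, had a difference of -0.48 ± 0.19 and did not pass (adjusted p = 0.0648), but passed without empty replicate 3 (-0.69, adjusted p = 2.11e-05), with quantile normalization (-0.48, adjusted p = 0.0376) and with library weights (-0.74, adjusted p = 2.63e-08). Relative to the other empty libraries, the list stood at -0.61 in empty replicate 3 and -0.42 in the NT-PGC1a group. Of the neuroendocrine markers 4 of 20 were measured, and 0 rose or fell (0 adjusted over the list alone), while 2 fell without empty replicate 3.

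Genes of mitochondrial metabolism are known PGC-1α targets. The lists of the respiratory complexes, the TCA cycle and fatty acid oxidation did not pass with camera, though fry called fatty acid oxidation (fry adjusted p = 0.0370). In respiratory complex I 3 of 37 subunit genes rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.680). NDUFS3 rose by 0.28 ± 0.06 and NDUFC2 differed by -0.48 ± 0.11 (log2, SE). In complexes II, III, IV and V 4 of 39 rose and 2 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.834). COX6A1 rose by 0.18 ± 0.04 and CYC1 by 0.17 ± 0.04, though CYC1 did not pass after removal of a GC and length trend (0.09, adjusted p = 0.0664). The camera direction of that list was up, while its median and mean were below 0, and the direction was down without empty replicate 3 (adjusted p = 0.434). Without empty replicate 3, 12 and 10 members of the 2 lists fell and 4 and 5 rose. The TCA cycle list had 3 rises and 5 falls among 20 (3 and 6 adjusted over the list alone, 4 and 9 without empty replicate 3, camera adjusted p = 0.338), with OGDH at -0.30 ± 0.06 and PDHA1 at -0.25 ± 0.06. CS, the citrate synthase gene, differed by 0.06 ± 0.04 and did not pass (adjusted p = 0.204), but passed with library weights (0.07, adjusted p = 0.0210). Of 24 genes of fatty acid oxidation 7 fell and 0 rose (7 and 0 adjusted over the list alone), with HADHB at -0.27 ± 0.05 and ETFDH at -0.38 ± 0.07. CPT2, the second carnitine palmitoyltransferase gene, named after its value was seen, was 1.66-fold lower (-0.73, adjusted p = 0.00673, and -0.89 without empty replicate 3). That list did not pass (camera adjusted p = 0.0777) but did without empty replicate 3 (11 fell, 2 rose, adjusted p = 0.0367, and adjusted p = 0.494 with an estimated correlation). CPT1A, the carnitine palmitoyltransferase gene, differed by -0.09 ± 0.04 and did not pass (adjusted p = 0.0938), but passed with median centring (-0.12, adjusted p = 0.0319), quantile normalization (-0.13, adjusted p = 0.0238) and library weights (-0.07, adjusted p = 0.0264). Relative to the other empty libraries, empty replicate 3 stood at -0.19 for complex I, -0.20 for the other complexes and -0.21 for fatty acid oxidation, against -0.08, -0.06 and -0.17 in the NT-PGC1a group.

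Among 15 mitochondrially encoded transcripts 2 rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.240). MT-RNR1, the small mitochondrial rRNA, rose by 0.85 ± 0.14 and MT-ND6, a complex I subunit gene, differed by -0.73 ± 0.14 (log2, SE). MT-RNR2, the large mitochondrial rRNA, was the other gene that rose (0.63), and is named after its value was seen. Of 24 regulators of mitochondrial biogenesis 9 rose and 3 fell (12 and 3 adjusted over the list alone, 12 and 5 without empty replicate 3, camera adjusted p = 0.0872). PPARGC1A itself is a member and one of those that rose, and without it 8 of 23 rose and 3 fell (camera adjusted p = 0.217). Over the list with PPARGC1A, empty replicate 3 was 0.25 above the other empty libraries, against 0.36 in the NT-PGC1a group. ESRRA, which encodes the nuclear receptor partner ERRα, rose by 0.24 ± 0.05 (adjusted p = 0.00820) and PPARD differed by -0.28 ± 0.05. The ESRRA call was lost where a log2 difference of at least 0.25 was required. TFAM, the mitochondrial transcription factor gene, and CYCS, which encodes cytochrome c, differed by -0.19 ± 0.09 and -0.18 ± 0.08 and did not pass (adjusted p = 0.0848 and 0.0844). Both passed without empty replicate 3 (-0.26, adjusted p = 0.00297, and -0.25, adjusted p = 0.00152) and with library weights (-0.32, adjusted p = 1.27e-05, and -0.30, adjusted p = 3.74e-06). Library weights gave empty replicate 3 a weight of only 0.050, so the 2 alternatives are not separate. In the mitochondrial ribosome list 14 of 38 rose and 1 fell, MRPL13, named after its value was seen (14 and 1 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.0308. The adjusted p = 0.650 with an estimated correlation. MRPL27 rose by 0.54 ± 0.08, MRPL9 by 0.44 ± 0.10 and MRPL12 by 0.27 ± 0.05. The list's preset camera call was also lost without empty replicate 3 (adjusted p = 0.0884), without NT-PGC1a replicate 2 (0.0761), with quantile normalization (0.207), with library weights (0.151) and after removal of a GC and length trend (0.0503). Without empty replicate 3 20 members rose and 6 fell. That library was 0.05 above the other empty libraries over this list, against 0.10 with NT-PGC1a.

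Of 9 measured mitochondrial antioxidant genes 3 rose and 1 fell (3 and 2 adjusted over the list alone, 3 and 4 without empty replicate 3, camera adjusted p = 0.783). The glutathione peroxidase genes GPX1 and GPX4 rose by 0.27 ± 0.05 and 0.28 ± 0.07 (log2, SE). SOD2, the mitochondrial superoxide dismutase gene, differed by -0.11 ± 0.06 and did not pass (adjusted p = 0.154), but passed without empty replicate 3 (-0.15, adjusted p = 0.0111) and with library weights (-0.18, adjusted p = 0.000397). In the NRF2 and glutathione list 1 of 19 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.911), and 8 rose and 3 fell without empty replicate 3. The list's median was above 0 and its mean and test below, and the test was above 0 without empty replicate 3 (adjusted p = 0.657). SLC7A11, the cystine transporter gene, differed by -0.97 ± 0.14 and GCLC, a subunit of the enzyme that starts glutathione synthesis, by -0.23 ± 0.05. HMOX1, the heme oxygenase gene, differed by -0.43 ± 0.21 and did not pass (adjusted p = 0.123), but passed without empty replicate 2 (-0.60, adjusted p = 0.0312) and with library weights (-0.53, adjusted p = 0.0156). Of the 5 measured metallothionein and metal response genes 1 rose, SLC30A1, named after its value was seen, and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.557), and 4 rose and 1 fell without empty replicate 3. In glycolysis 6 of 21 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.0506), with PDK1 at -0.35 ± 0.07 and HK1 at 0.35 ± 0.08. 13 fell without empty replicate 3, with a camera adjusted p of 0.0317 and an adjusted p of 0.737 with an estimated correlation, and that library stood at -0.30 relative to the other empty libraries, against -0.25 with NT-PGC1a. The hypoxia list had 4 rises and 4 falls among 16 (4 and 4 adjusted over the list alone, camera adjusted p = 0.911), with a median below 0 and a mean and test above it.

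Cytosolic ribosomal protein genes rose by a small amount, in 32 of 51 members with 0 falls (37 and 0 adjusted over the list alone). The median was 0.12 (camera adjusted p = 7.19e-09, and adjusted p = 0.614 with an estimated correlation), and RPS19 and RPS3 rose by 0.23 ± 0.04 and 0.18 ± 0.04 (log2, SE). Empty replicate 3 was 0.06 above the other empty libraries over the list, against 0.13 with NT-PGC1a. Of 32 MYC targets 13 rose and 3 fell (13 and 3 adjusted over the list alone, 17 and 6 without empty replicate 3, camera adjusted p = 0.0842), and the ribosome assembly genes RRP9 and BOP1 rose by 0.41 ± 0.09 and 0.32 ± 0.07. MYC itself differed by -0.19 ± 0.10 and did not pass (adjusted p = 0.143), but passed without empty replicate 3 (-0.30, adjusted p = 0.000111) and with library weights (-0.34, adjusted p = 1.14e-06). Of 17 genes of polyamine metabolism 7 rose and 2 fell (7 and 2 adjusted over the list alone, 9 and 5 without empty replicate 3, camera adjusted p = 0.476). ODC1, which encodes ornithine decarboxylase, the first enzyme of polyamine synthesis, differed by -0.51 ± 0.13 (adjusted p = 0.0112), and DOHH rose by 0.44 ± 0.10. The ODC1 value of empty replicate 3, 14.19, lay at the NT-PGC1a mean of 14.22. Over the MYC targets that library was 0.142 above the other empty libraries, against 0.139 in the NT-PGC1a group. Over polyamine metabolism it was 0.146 above them, against 0.139.

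Of 33 lysosome and autophagy genes 12 rose and 1 fell (12 and 0 adjusted over the list alone, camera adjusted p = 0.110). TFEB, a master regulator gene of lysosomes, rose by 0.50 ± 0.09 and GPNMB by 1.42 ± 0.27 (log2, SE), and 17 rose and 6 fell without empty replicate 3. That library was 0.27 above the other empty libraries over the list, against 0.26 with NT-PGC1a. In the list of integrins, cytoskeleton and matrix 9 of 31 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.338). ACTA2 and THBS1, which encodes thrombospondin, rose by 1.52 ± 0.18 and 1.37 ± 0.21. The end of ACTA2 overlaps that of FAS, which lies on the other strand and also rose. The strand setting is not given, so reads of the overlap could not be told apart. Of 17 epithelial markers 5 rose and 4 fell (5 and 4 adjusted over the list alone, 9 and 5 without empty replicate 3, camera adjusted p = 0.483), and the tight junction genes CLDN3 and CLDN4 rose by 0.47 ± 0.06 and 0.29 ± 0.05. Of 10 measured EMT genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.102), with FN1 at 0.36 ± 0.06 and SNAI2 at 1.38 ± 0.26, and 6 rose and 1 fell without empty replicate 3. The cholesterol biosynthesis list had 4 rises and 4 falls among 23 (3 and 4 adjusted over the list alone, camera adjusted p = 0.880), with a median and test above 0 and a mean below it. It had 8 and 8 without empty replicate 3, where both its median and test were below 0 (adjusted p = 0.769). Fatty acid synthesis had 4 rises and 8 falls among 23 (4 and 10 adjusted over the list alone, camera adjusted p = 0.383).

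Markers of other cells that a culture could hold passed the expression filter in part. Of the fibroblast markers 4 of 10 were measured, of the endothelial markers 2 of 8 and of the basal prostate markers 2 of 6, and 0 of these rose or fell. The most abundant of them was COL1A1, a collagen gene, at a mean rlog of 10.9. 5 of 10 markers of hormone-insensitive prostate lines were measured and 0 rose or fell, ITGB4 being the most abundant at a mean rlog of 8.92. Of 9 leukocyte markers only CD68, a lysosomal protein gene, was measured, and it rose by 0.44 ± 0.16 (log2, SE, adjusted p = 0.0465). Of 6 markers of embryonal kidney and cervical lines 3 were measured, and POU4F1 fell (-0.57 ± 0.18, adjusted p = 0.0243). CD68 and POU4F1 are named after their values were seen.

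12 of the 35 lists tested passed with camera's preset correlation, and 0 passed with an estimated correlation. With the exact permutation test, whose smallest p is 0.00794, 0 genes passed after adjustment over the 15629 genes, while 8525 genes had an unadjusted p under 0.05 in limma.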

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

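The tests of where empty replicate 3 lies, of the histone rise and of the interferon-stimulated genes were chosen after the data were seen. What would count for or against GC content and length was set before that test's own result was seen. Each value below is the gap between the highest or lowest library and its nearest neighbour, divided by the range of its group of 5, and was picked out above 0.71. Chance picks out about 1 in 20 groups. Over 129 results in each group 63 values were picked out, of which 57 belonged to empty replicate 3, 5 to NT-PGC1a replicate 2 and 1 to NT-PGC1a replicate 3.

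Empty replicate 3 stood apart among the genes with the greatest rises and falls, at 0.806 for ANGPT2, 0.82 for TCIM, 0.848 for MRGPRE, 0.941 for ENC1, 0.77 for FAM229A, 0.884 for LBR, 0.829 for PDE3B, 0.89 for RFXAP and 0.89 for PDK3. For p53, apoptosis, stress and inflammatory genes it did so at 0.957 for CDKN1A, 0.787 for BTG2, 0.838 for FAS, 0.799 for PPM1D, 0.857 for BCL2L1, 0.81 for BBC3, 0.913 for ATF3, 0.858 for NFKBIA and 0.876 for BCL3. For androgen-regulated genes the values were 0.883 for KLK3 and 0.783 for ZBTB10, and for genes of growth and the cell cycle 0.719 for ODC1, 0.716 for RFC4, 0.806 for KIF11, 0.88 for MKI67 and 0.906 for H1-2. Genes of metabolism gave 0.881 for NDUFC2, 0.863 for OGDH, 0.723 for MRPL9, 0.79 for GPX1, 0.76 for GPX4 and 0.842 for HK1. Other genes gave 0.766 for TFEB, 0.884 for GPNMB, 0.886 for ACTA2, 0.735 for CLDN3, 0.784 for CLDN4, 0.876 for SNAI2, 0.843 for SNHG12 and 0.861 for GAS5.

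For the mean of a whole list, empty replicate 3 stood apart at 0.72 for complex I, 0.727 for the other respiratory complexes, 0.914 for fatty acid oxidation, 0.863 for mitochondrial biogenesis, 0.734 for NRF2 and glutathione, 0.829 for androgen-regulated genes, 0.836 for G2/M and mitosis, 0.764 for histones, 0.922 for p53 targets and 0.845 for apoptosis regulators. The values were 0.892 for interferons and RNA sensors, 0.845 for NF-kB and inflammatory genes, 0.86 for metallothioneins, 0.881 for lysosome and autophagy, 0.803 for EMT genes, 0.856 for immediate early genes, 0.884 for cytosolic ribosomal proteins and 0.978 for the first principal component. NT-PGC1a replicate 2 stood apart at 0.771 for NUF2, 0.831 for GPNMB, 0.712 for RPS19, 0.756 for the list of integrins, cytoskeleton and matrix and 0.737 for the first principal component. NT-PGC1a replicate 3 stood apart at 0.83 for RFC3.

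Empty replicate 3 lay 97.4% of the way from the other 4 empty libraries to the NT-PGC1a mean over all tested genes. The displacements correlated at 0.901 across genes, or 0.876 with the controls split between them. In 100 simulations of an unchanged group with shared controls, and with noise independent between genes, the correlation was 0.334. The covariances were 0.247, 0.243 with split controls and 0.00521 in the simulations. An exchange with an NT-PGC1a library is argued against by PPARGC1A, which lay 3.40 log2 units below the lowest NT-PGC1a library, and admixed NT-PGC1a RNA by the share that PPARGC1A allows, 0.789%. A trend with GC content and length is argued against by the 97.5% of the way that stayed after its removal. A culture state that empty replicate 3 shares with the NT-PGC1a cultures, and that does not need the delivered mRNA, cannot be told apart from other origins of the library with the correlation of 0.876, because 1 library carries the pattern and no label describes such a state. A library from another treatment without PPARGC1A message was not tested, and the effect of NT-PGC1a itself stays open for the genes that moved in this library too.

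Replication-dependent histone RNAs rose with a median of 0.90, while a further rise was seen for 1 of the 2 entries of the small nuclear RNA RN7SK (2.28, adjusted p = 0.00528, and 0.12 for the other). The G1/S and DNA replication list did not rise with the histones, and its median was -0.362. That fall was known before the rule for this test was set, and RNA levels do not count cells in S phase. A larger share of cells in S phase is therefore not excluded. Carry-over of RNA without a poly(A) tail into the NT-PGC1a libraries cannot be told apart from a change in the cells. The median of the other such RNAs that were measured, 0.356, lies between what the explanation needs and what would exclude it. Only 3 were measured, of which 2 rose. RN7SK was set aside from these as part of the pattern, and its 2 entries, 2.28 and 0.12, lie on either side of that median. The entry that rose was not a counted member of the RNA quality list. Which library kit was used is not given in the sources used here. The NT-PGC1a treatment itself stays among the open explanations.

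Interferon-stimulated genes rose in the NT-PGC1a group, and 19 list members rose without empty replicate 3. The median of these members in empty replicate 3 was 80.0% of the way to the NT-PGC1a mean, so many of them may be part of what that library shares. However, 6 of the 19 lay under 25% of the way. Over the whole list that library stood 0.14 above the other empty libraries, against 0.53 in the NT-PGC1a group. For IFIT1, IFIT2, IFIT3, OASL and RSAD2 the highest share was 15.6%, but these 5 genes were picked out by their low share in that library, so this is not a test, and whether they are part of what it shares stays open. A response to delivered RNA as such, whatever it encodes, cannot be told apart from a response to the encoded protein, because 0 libraries with a control mRNA were among those analysed.

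Regroupings of the 10 libraries into 5 and 5, of which 100 were drawn, gave as many changed genes as the real 6969 in 3 cases, the real one included, and the highest other count was 8564. A regrouping has no direction of its own, so for the other regroupings the larger of the counts of higher and lower genes was taken. Counted in this way 4 gave as many as the real 3534 higher genes and 4 as many as the real 3435 lower genes, the real one included, and the highest other count was 4584. The 3 counts thus passed the 0.05 level among the regroupings drawn, out of 126 possible. Apart from the real one, every regrouping drawn that called any gene exchanged empty replicate 3 with an NT-PGC1a library. The exchanges with NT-PGC1a replicate 3 and with NT-PGC1a replicate 5 were not among those drawn, so these tallies depend on the draw. The counts therefore reflect how these libraries cluster. The labels do not say that the libraries were separate cultures, so chance between cultures is not excluded. The split with 8564 genes exchanged empty replicate 3 with NT-PGC1a replicate 2, and another with 7261 exchanged it with NT-PGC1a replicate 4, which points to the structure of the samples described above. For the 12 gene lists chance is not excluded, since 35 of the 100 gave as many, and the highest other count was 18.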

How the results depend on the processing

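The removal of the GC and length trend, and the leaving out of empty replicate 3 together with an estimated correlation, were chosen after the data were seen, as were the leaving out of PPARGC1A from its list, which left the number of lists past the threshold at 12, and the alternatives for the 2-fold counts and for the directions of lists that did not pass. None of the genes named by the rule and none of the 12 lists that passed reversed its direction, and genes named after their values were seen were not run under the alternatives as a set. Of the 35 lists tested, 8 turned under at least 1 alternative. They are complex I, the other respiratory complexes, mitochondrial antioxidants, NRF2 and glutathione, hypoxia, interferons and RNA sensors, heat shock and cholesterol biosynthesis. 0 of the 8 passed before or after the turn, where the lowest camera adjusted p was 0.142, and the cause was not tested. PPARGC1A was called with a log2 difference between 4.19 and 4.47 under all alternatives except the exact permutation test, where its difference of 4.293 had an adjusted p of 0.0529. The smallest p that 252 relabellings can give, 0.00794, was reached by 2345 of the 15629 genes, and 0.0529 is its adjusted value. That test called 0 genes in all, 0 higher and 0 lower, against 8525 genes at an unadjusted p under 0.05 in limma. Library weights raised the counts to 12027 changed, 6203 higher and 5824 lower. The weight was 0.050 for empty replicate 3 and 0.29 for the next lowest, NT-PGC1a replicate 2. A result that passed with library weights is thus not separate from its passing without empty replicate 3. Leaving out 1 library moved the counts between 4300 and 10662, 2173 and 5499, and 2127 and 5163. The upper values were without empty replicate 3 and the lower values without empty replicate 4. The counts of at least 2-fold higher and lower genes, 271 and 123, were 515 and 377 with library weights, 208 and 72 with a floor on low values, 0 and 0 with the exact permutation test, and between 217 and 478 and between 81 and 347 with 1 library left out. The number of gene lists past the threshold was 12, 20 without a filter, 20 with fry, 0 with an estimated correlation, and 0 without empty replicate 3 and with an estimated correlation. Besides the 12, fry called fatty acid oxidation, mitochondrial biogenesis with PPARGC1A as a member, MYC targets and polyamine metabolism. It also called lysosome and autophagy, integrins, cytoskeleton and matrix, epithelial markers and EMT genes (fry adjusted p from 0.00188 for integrins to 0.0468 for MYC targets). The replicate number as a block gave 6596 changed genes, 3311 higher and 3285 lower, and 13 lists. KLK3, TFAM and MKI67, which had not passed, passed with the block (adjusted p = 0.0289, 0.0476 and 0.0249). Deviations of same-numbered libraries correlated at -0.140, 0.325, 0.125, 0.0458 and -0.185 across genes, and not every library correlated best with its own number. These deviations are from group means that include empty replicate 3, so they do not show whether the numbers pair the libraries. Over the genes named by the rule and the alternatives 1884 comparisons stayed on their side of the threshold, 23 passed only under the alternative and 90 were lost, 82 of the latter with the exact permutation test. A required log2 difference of at least 0.25 lost 7, whose differences were smaller in size. They are ESRRA, COX6A1, CYC1, PDHA1, GCLC, RPS19 and RPS3. Removal of the GC and length trend lost 1, CYC1. For the lists that passed, 233 stayed and 31 were lost. The depth of the libraries is unknown, so a difference in a weakly expressed gene that was not seen here is not shown to be absent.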

Other observations

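All tests in this part were chosen after the data were seen. Without empty replicate 3, 825 genes differed at least 2-fold, 478 higher and 347 lower. In 768 of them empty replicate 3 lay over 50% of the way to the NT-PGC1a mean, and in 15 it lay under 25%, all of them higher with NT-PGC1a. These 15 are PPARGC1A, IFIT1, IFIT2, IFIT3, OASL, RSAD2, KRT81, H3C4, H3C10, H2BC18, EGR1, CYP11A1, MMD, AGAP2 and 1 unnamed gene. RSAD2, which encodes the antiviral protein viperin, rose by 1.81 ± 0.18 (log2, SE) over all libraries, CYP11A1, the enzyme that starts steroid hormone synthesis from cholesterol, by 1.27 ± 0.14, and AGAP2 by 1.05 ± 0.16, and MMD rose 2.14-fold. KRT81 rose by 1.77 ± 0.32, but it is close in sequence to other hair keratin genes, so its value is uncertain. KRT81 and H3C4 averaged 3.58 and 3.97 in the other empty libraries, so they passed the filter of 4 only through their NT-PGC1a values. Of the 8 interferon-stimulated genes of the list that differed at least 2-fold, 5 are among the 15, and of 11 such members of the histone list 2 are. The 15 genes were selected by their value in 1 library, and IFIT1, IFIT2 and IFIT3 are neighbours, so no p is given for these counts, and they do not test what is tied to the delivered mRNA.

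The integrated stress response list did not pass (camera adjusted p = 0.680), and 5 of its 11 members that rose and 3 of its 7 that fell are named here after their values were seen. DDIT3, which encodes the transcription factor CHOP, rose by 1.84, GDF15 by 1.54, PPP1R15A by 1.49, TRIB3 by 1.12 and the transporter gene SLC3A2 by 0.93 on the log2 scale. PSAT1 differed by -0.71, PSPH by -0.44 and the transporter gene SLC7A5 by -0.72. In empty replicate 3 DDIT3 lay 97.9% and PSAT1 77.0% of the way to the NT-PGC1a mean. Among the mitochondrially encoded genes, the rRNAs MT-RNR1 and MT-RNR2 rose by 0.85 and 0.63, while MT-CO3 and MT-CYB differed by -0.54 and -0.35. Of the 15 measured, 7 fell and 6 did not pass. Over the list empty replicate 3 stood at -0.04 relative to the other empty libraries, against -0.10 in the NT-PGC1a group, and for MT-RNR1 it lay 51.2% of the way.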
